A study of Arabidopsis thaliana with 12 samples.

How the data were processed

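RNA of whole Arabidopsis thaliana seedlings was measured on 12 expression arrays, 3 for each of 4 groups: wild type and an erf5/6 double mutant, each treated for 30 min with water or with 1 µM chitooctaose at 14 days of age. Per the labels' protocols, seedlings were grown under constant light, total RNA was extracted with Trizol, and biotin-labelled antisense RNA was made from it with an oligo(dT) primer. The deposited values are probe set intensities on a linear scale, 1 column per array; how the authors summarized the probes, corrected the background or scaled the arrays is not given in the sources used here. The deposited columns had medians between 77.0 and 83.2 and between 186 and 247 values at or below 1 on each array, so they were close in scale but not identical. Samples were grouped by the genotype, treatment and replicate number in the labels, which name 3 biological replicates per group.

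The intensities were quantile normalized between arrays, values below 16 were set to 16, and log2 was taken. Between 23.4% and 24.8% of the values of an array lay below that floor. The 4066 probe sets at the floor on all 12 arrays were left out of the tests, although the design fixed before the data were examined speaks of all probe sets. Keeping them was run as an added alternative, and ended the calls of ARR15 and AT5G48570 in wild type, of AT1G49200 and AT2G43620 in the mutant, and of AT5G55570 and 1 unnamed probe set between the genotypes. Gene names came from the platform annotation of the arrays, updated by gene identifier through a RefSeq gene table of assembly TAIR10.1. Of the 22746 probe sets, 13513 were assigned to 1 gene, 503 to several and 8730 to none in that table; 13436 of those with 1 gene matched the RefSeq table. Genes were named only from probe sets with 1 gene, and 11933 of these carry a locus code in place of a symbol. Counts of calls are counts of probe sets.

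Differences were tested with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison, and called at an adjusted p under 0.05. The comparisons were the response to chitooctaose in each genotype, the difference between these responses, the genotype difference in each treatment, and the average effects of chitooctaose and of genotype. All p-values are two-sided. A probe set at the floor on all arrays of 1 group has only a bound there; its change is given as at least N-fold, the group mean against the floor, and it was not ranked with the others. Single genes were named by a rule fixed before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among called probe sets of 1 gene whose groups did not overlap, which chance gives for 10% of probe sets with 3 arrays against 3. Where under 5 probe sets were called for the difference between the responses, it took the 5 lowest p-values in each direction. It also took up to 4 members with the lowest p of each gene list.

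Of 31 gene lists fixed before the data were examined, with 436 entries, 71 entries were measured by a probe set of 1 gene and 67 genes were above the floor on at least 1 array. The 11 lists with at least 3 such genes were tested with camera at a preset correlation of 0.01, then with a correlation estimated per list, and with fry, each adjusted over these lists. A gene with several probe sets was represented by the one with the highest mean. Another 37 family lists were added after the data had first been examined; 31 of them held at least 3 tested genes and were adjusted as a group of their own. The size of the response was tested with fry over probe sets called for the average chitooctaose effect with at least 2-fold change.

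The procedure was tested on simulated data with the real means and spreads and 200 changed probe sets. The changed ones were drawn only from probe sets well above the floor, and the noise was independent between probe sets and arrays. For the wild-type response the procedure recovered 93.0% of 2-fold and 100% of 4-fold changes, with 7 false calls. For the genotype difference in water it recovered 99.0% and 100%, with 16 false calls. For the difference between the responses it recovered 83.0% and 100%, with 13 false calls. Recovery among dimmer probe sets was not simulated. In 100 simulations without a difference in response size the fry test gave a p under 0.05 in 5. Their median differences lay between -0.0218 and 0.0191, and the real one, 0.0458, lay outside that range. The real probe sets that rose had an estimated correlation of 0.06, which the simulations lacked. The 5 of 100 therefore does not show how the test behaves on the real arrays. Alternatives were the deposited values without normalization, median centring, a filter on the 40% dimmest probe sets, an intensity trend with a robust prior, array weights, only the arrays of the groups compared, the replicate number as a block, a 2-fold minimum change, an added offset of 32 in place of the floor, an estimated correlation, no minimum change, and leaving out each array in turn. No array was excluded from the reported values, and no pair of arrays held identical columns.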

Results

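Transcript levels were measured in whole Arabidopsis thaliana seedlings of 2 genotypes, wild type and an erf5/6 double mutant, on 12 expression arrays. ERF5 and ERF6 are ethylene response factors, transcription factors of the AP2/ERF family. Seedlings 14 days old were treated for 30 min with 1 µM chitooctaose, a soluble oligosaccharide fragment of the fungal cell wall polymer chitin, or with water. Each of the 4 combinations of genotype and treatment had 3 arrays, which the labels call biological replicates. The arrays held 22746 probe sets, of which 18680 lay above the floor on at least 1 array and were tested. No probe set was named for ERF5 or ERF6 in the gene table used here, so the genotype labels could not be checked against the targeted transcripts. That table left 8730 probe sets without a gene, and the targeted transcripts may be measured among them.

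The main separation among the arrays was by treatment. Principal component 1 carried 64.9% of the variance and split the chitooctaose arrays from the water arrays. Within a group the lowest correlation between arrays was 0.984, and between treatments the correlations lay between 0.953 and 0.964. Component 2 carried 7.42%, with array 2 of chitooctaose-treated wild type at -0.67 and array 1 of water-treated wild type at -0.49. The other 10 arrays lay between -0.14 and 0.29 on that component. The number of arrays limited the precision: the median 95% confidence interval of a difference between 2 groups reached 0.27 on the log2 scale to each side, and 0.39 for a difference between the responses of the 2 genotypes.

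The first comparison asked which transcripts changed in wild-type seedlings within 30 min of chitooctaose. AT1G07160, which encodes a PP2C-type protein phosphatase, rose by 5.83 ± 0.08 on the log2 scale (SE, n = 3 arrays per group). AT2G22880, a VQ-motif gene, rose by 5.47 ± 0.30, the zinc finger gene STZ by 5.16 ± 0.18, and AT1G24140, a matrix metalloproteinase gene, by 5.07 ± 0.08. The normalized intensity of STZ went from 71.8 in water to 2562 in chitooctaose. The other genes among the 10 largest measured rises were AT4G28460, AR781, the TIR-domain genes AT1G66090 and AT1G72920, AT5G05300, which encodes an IDA-like peptide, and AT2G32030, an acetyltransferase family gene, between 4.41 and 4.65. Adjusted p-values of these 10 genes from limma lay at 4.5e-07 or below.

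Several transcripts were at the intensity floor on all 3 water arrays of wild type and well above it after chitooctaose. AT3G02840, an ARM-repeat gene, was at least 63.1-fold higher (adjusted p = 8.18e-11), AT3G01830, an EF-hand calcium sensor gene, at least 25.2-fold (adjusted p = 2.76e-10), and the secreted peptide precursor genes AT2G23270 and AT4G37290 at least 22-fold and 18.4-fold. The NAC factor gene AT3G12910 was at least 11.4-fold higher, the PLATZ gene AT1G43000 at least 7.19-fold and the AP2/ERF gene AT1G22810 at least 7.03-fold.

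Falls were smaller than rises. Among genes that fell, AT1G69760 changed by -1.45 ± 0.19, AT5G61590, an AP2/ERF gene, by -1.43 ± 0.13, AT2G36090 by -1.34 ± 0.14 and AT2G21560 by -1.34 ± 0.10. AT5G03230 (-1.28), AT1G49200 (-1.26), AT3G02930 (-1.22), AT5G61570 (-1.20), AT1G78170 (-1.16) and AT3G25870 (-1.11) completed the 10 largest measured falls, all with an adjusted p of 0.0108 or lower. With an offset of 32 in place of the floor 5 of these falls were over 1.5 times smaller: -0.67 for AT2G36090, -0.84 for AT1G49200, -0.56 for AT3G02930, -0.57 for AT5G61570 and -0.72 for AT3G25870, all still called. In all, limma called 1894 of 18680 probe sets in wild type, 1132 higher and 762 lower. Of these 1894, 1051 had 1 gene, 806 no listed gene and 37 several, and the rankings above cover only those with 1 gene. The count of falls depended on single arrays: 354 or 431 without array 1 or 2 of water-treated wild type, 379 without array 3 of chitooctaose-treated wild type and 449 without both arrays that stood apart on component 2, against 358 with only the arrays compared and 1269 with array weights. A change of at least 2-fold was seen for 631 of the higher and 34 of the lower probe sets, and a change of at least 4-fold for 283 and 0. At an unadjusted p under 0.05, 4433 probe sets were counted, against 934 given by chance.

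Gene lists chosen before the data were examined showed which measured members of named groups took part. Over all lists, only 71 of 436 entries had a probe set of 1 gene in the gene table used. Many members, such as WRKY33 and WRKY40, had none there, so a list result does not stand for its whole family. All 3 measured WRKY transcription factor genes rose in wild type, WRKY53 by 4.32, WRKY22 by 3.53 and WRKY6 by 2.37 (3 of 3 also when adjusted over the list alone). With camera, the WRKY list stood above the other probe sets (adjusted p = 1.22e-09, and adjusted p = 0.00176 with an estimated correlation). The 3 measured U-box ubiquitin ligase genes of immune signalling, PUB22 (2.81), PUB23 (3.36) and PUB24 (3.03), rose as well, 3 of 3 when adjusted over the list alone (camera adjusted p = 9.86e-10, and adjusted p = 0.00176 with an estimated correlation). Of 8 tested calcium signalling genes 5 rose, and 5 when adjusted over the list alone. They were the calcium sensor genes CML37 (at least 15.7-fold, from the floor), AT5G39670 (2.96), CML38 (2.94), CML42 (1.78) and CML23 (1.73); CML43, CML41 and AT3G47480 were not called, with changes of -0.01, 0.08 and -0.03. The calcium list had a camera adjusted p of 4.85e-09, and adjusted p = 0.00176 with an estimated correlation.

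The remaining lists were smaller or moved less in wild type. Of 3 oxidative burst genes the peroxidase gene AT1G14550 rose by 1.74, 1 of 3 also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0588). Of 3 stress zinc finger genes STZ rose, while AT2G28200 had -0.32 (adjusted p = 0.0616) and AT3G53600 0.05; adjusted over the list alone 2 of 3 were called, and the list did not pass (camera adjusted p = 0.122). The number of lists called was 5 rather than 3 when array 2 of water-treated wild type was left out, and 5 when the fit held the wild-type arrays alone. None of the 6 measured chitinase genes was called with limma, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05; their median change was 0.34 (camera adjusted p = 0.122), although fry, which tests the list without reference to other genes, gave an adjusted p of 0.035. The touch-inducible xyloglucan transferase genes XTH18 and XTH19 rose by 2.06 and 0.99, the receptor-associated kinase gene BIK1 by 1.05, SAG101, which encodes a partner of EDS1 in immune signalling, by 1.00, and the jasmonate biosynthesis gene OPCL1 by 1.67. CCR2, a cinnamoyl-CoA reductase gene of lignin synthesis, was at least 3.12-fold higher, from the floor in water. Each of these genes also passed when adjusted over its list alone. With the offset, AT1G14550 had 1.08 and CCR2 0.91.

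The cytokinin response regulator gene ARR15 was lower, at -0.71 (adjusted p = 0.0259; -0.41 with the offset), 1 of 2 in its list by either adjustment. That call was lost without array 1 or 3 of water-treated wild type (adjusted p = 0.0887 and 0.086) and without array 2 or 3 of chitooctaose-treated wild type (0.0691 and 0.0894). It was also lost with floor-constant probe sets kept (adjusted p = 0.0602), with only the arrays compared (0.0894) and without both wild-type arrays that stood apart on component 2 (0.166). In the heat shock list 1 of 3 genes was called lower, AT5G48570 (-0.50, adjusted p = 0.0423), and 1 when adjusted over the list alone, with a camera adjusted p of 0.931. That call held without array 1 or 3 of chitooctaose-treated mutant or array 2 of chitooctaose-treated wild type, and was lost without any of the other 9 arrays, up to an adjusted p of 0.123 without array 3 of chitooctaose-treated wild type. For AT5G48570 the adjusted p was 0.0778 with floor-constant probe sets kept, 0.0952 with only the arrays compared and 0.0749 without both wild-type arrays that stood apart. The 3 tested genes each of the abscisic acid and cold, auxin, root marker and reference lists gave 0 calls with limma, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Among them, COR47 had -0.05, GH3.3 0.10, the root gene PYK10 0.03 and the reference gene PEX4 -0.05. The green tissue genes LHCB4.1 (0.05) and RCA (-0.04) were not called either, with 0 of 2 at an unadjusted p under 0.05. In the lists with 1 or 2 tested genes, those not called over all probe sets in either genotype included the clock gene GI (0.08 in wild type), the ethylene signalling gene EIN3 (0.08), ORA47 (0.19), the jasmonate signalling genes MYC3 (-0.09) and MYC4 (-0.40), the immune receptor gene EFR (0.21), the flavonoid gene DFR (-0.36) and the glucosinolate genes BCAT4 (-0.15) and UGT74B1 (-0.34). Of these, UGT74B1 passed when adjusted over its list alone.

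**Figure D1:**
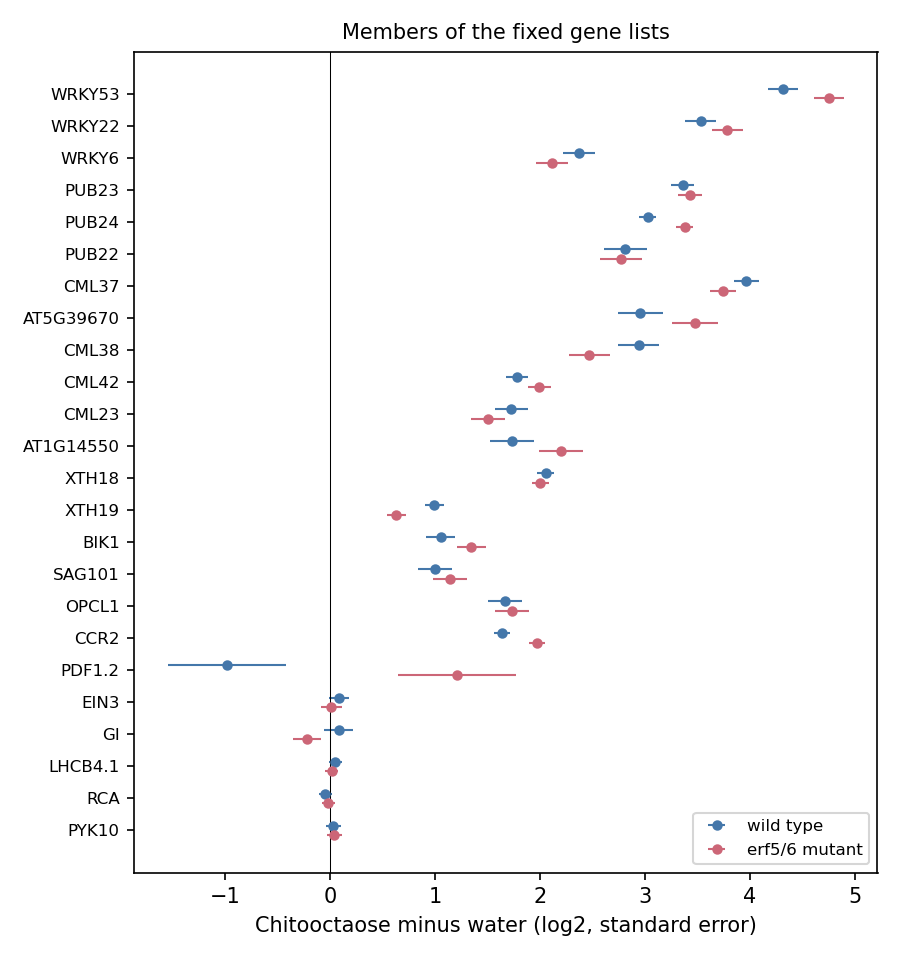
Change after chitooctaose of 24 members of the gene lists on the horizontal axis (log2, chitooctaose minus water), in wild type (blue) and in the erf5/6 mutant (red); points are limma estimates from 3 arrays per group and bars the standard error. WRKY and PUB genes and the 5 called calcium signalling genes lie between 1.5 and 4.76 in both genotypes, PDF1.2 has the widest bars, and the values of CML37 and CCR2 are lower bounds because both were at the floor in water.

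The same question was put to the erf5/6 mutant. There AT1G07160 was at least 64.6-fold higher, from the floor on all 3 mutant water arrays (adjusted p = 8.07e-12). AT2G22880 rose by 5.63 ± 0.30 (SE, n = 3 arrays per group), STZ by 5.17 ± 0.18, AT1G66090 by 5.05 ± 0.19, AT1G24140 by 4.88 ± 0.08, AT5G05300 by 4.88 ± 0.12 and WRKY53 by 4.76 ± 0.14. AT4G28460 (4.87), AT3G10930 (4.55), which encodes an IDA-like peptide, AT1G26380 (4.49), an FAD-linked oxidase gene, and AT1G58420 (4.44) completed the 10 largest measured rises. AT3G02840 was at least 66.0-fold higher from the floor, AT3G01830 at least 23.9-fold, AT4G37290 at least 20.2-fold and AT2G23270 at least 17.9-fold. Among named genes AT5G61590 fell the most in the mutant, by 1.62 on the log2 scale, with a standard error of 0.13. It was followed by AT5G03230 (-1.51), AT1G64405 (-1.36), the acyltransferase family gene AT2G40230 (-1.35), AT2G44940 (-1.31), an AP2/ERF gene, WAG2 (-1.23), a protein kinase gene, AT3G51400 (-1.20), AT3G50300 (-1.17) and AT4G16447 (-1.14). With the offset these were -0.67 for AT1G64405, -0.79 for AT2G44940, -0.56 for AT3G51400, -0.59 for AT3G50300 and -0.76 for AT4G16447, all still called. AT1G49200 also fell, at -1.17 (adjusted p = 0.0176), a call lost without array 3 of water-treated mutant (adjusted p = 0.0743) or array 2 of chitooctaose-treated mutant (adjusted p = 0.0711), and with floor-constant probe sets kept (adjusted p = 0.0546).

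In the mutant, limma called 1608 probe sets, 1111 higher and 497 lower, or 30.9% lower. Of these 1608, 866 had 1 gene and entered the rankings, 709 had no listed gene and 33 several. With the deposited values taken without further normalization the mutant had 1275 higher and 254 lower, or 16.6% lower. Falls in the mutant numbered 309 without array 3 of water-treated mutant, 322 or 302 without array 1 or 3 of chitooctaose-treated mutant, and 921 with array weights. Changes of at least 2-fold numbered 649 higher and 47 lower, and changes of at least 4-fold 295 and 0. All 3 WRKY genes rose again (WRKY22 by 3.79, WRKY6 by 2.12), as did PUB22 (2.77), PUB23 (3.43) and PUB24 (3.38), and both lists held 3 of 3 when adjusted over the list alone. Camera adjusted p-values were 2.24e-10 for WRKY factors and 1.32e-10 for the ubiquitin ligases (adjusted p = 0.00126 for both with an estimated correlation). Of the 8 calcium signalling genes 5 rose, CML37 by at least 13.4-fold, AT5G39670 by 3.48, CML38 by 2.47, CML42 by 2.00 and CML23 by 1.5, with 5 when adjusted over the list alone (camera adjusted p = 6.57e-10, and adjusted p = 0.00126 with an estimated correlation).

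The oxidative burst list passed in the mutant (camera adjusted p = 0.0131), a call lost with an estimated correlation (adjusted p = 0.0591 with an estimated correlation); AT1G14550 rose by 2.2 (1.34 with the offset), and AT5G64120, a peroxidase gene, reached 0.63 (adjusted p = 0.0707), so 1 of 3 was called and 2 when adjusted over the list alone. In the stress zinc finger list STZ rose and AT2G28200 fell by 0.60, 2 of 3 by either adjustment (camera adjusted p = 0.373). The chitinase gene AT2G43620 rose by 1.01 (adjusted p = 0.0204), 1 of 6 by either adjustment, and the list did not pass (camera adjusted p = 0.356). That call was lost without array 2 or 3 of water-treated mutant (adjusted p = 0.066 and 0.0711) or array 1 of chitooctaose-treated mutant (adjusted p = 0.0813), and with floor-constant probe sets kept (adjusted p = 0.0591). XTH18 (2.01), XTH19 (0.63), BIK1 (1.35), SAG101 (1.14) and OPCL1 (1.73) rose, CCR2 was at least 3.92-fold higher (1.13 on the log2 scale with the offset), and ARR15 was at -0.78 (adjusted p = 0.0157; -0.51 with the offset), lost without array 1 of water-treated mutant (adjusted p = 0.0661) or array 1 or 2 of chitooctaose-treated mutant (adjusted p = 0.0523 and 0.0582). The heat shock, abscisic acid and cold, auxin, root marker and reference lists gave 0 calls in the mutant with limma and 0 when adjusted over the list alone; at an unadjusted p under 0.05, 1 auxin gene and 1 root gene were counted. The green tissue genes LHCB4.1 and RCA were at 0.02 and -0.01. Adjusted over their lists alone, UGT74B1 (-0.41), HCT (-0.29), UF3GT (-0.62) and EFR, at the floor on all mutant water arrays, also passed in the mutant, and over all probe sets they did not.

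The responses of the genotypes were then set side by side. They share no control arrays, but they share 1 estimate of the spread per probe set, which favours calls in both. The counts given for independent lists do not allow for this. Of the probe sets called higher, 976 were higher in both genotypes, 86.2% of those in wild type and 87.8% of those in the mutant, against 67.3 for independent lists. Of the probe sets called lower, 227 were lower in both, 29.8% of those in wild type and 45.7% of those in the mutant, against 20.3 for independent lists, and 2 probe sets were called in opposite directions. With single arrays left out, 23.4% to 47.2% of the falls in wild type and 35% to 58.9% of those in the mutant were shared. With only the arrays compared, so with a separate spread for each genotype, 35.5% and 32.5% of falls and 88% and 82% of rises were shared. Of the 689 called in wild type alone, 627 (91.0%) had the same sign in the mutant, and of the 403 called in the mutant alone, 373 (92.6%) had the same sign in wild type. Across the 18680 probe sets, which are not independent replicates, the log2 changes of the 2 genotypes had r = 0.905.

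**Figure D2:**
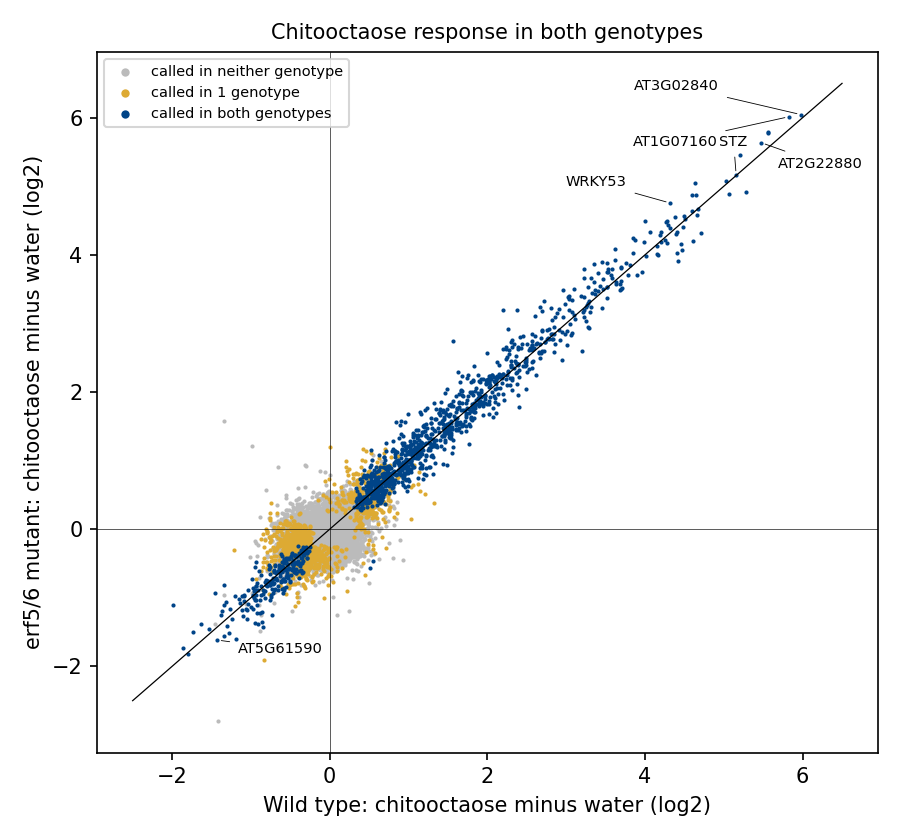
Each point is 1 of 18680 probe sets, with its log2 change after chitooctaose in wild type on the horizontal axis and in the erf5/6 mutant on the vertical axis (group means of 3 arrays); colours show calls in neither, 1 or both genotypes, and the line marks equal changes. Probe sets called higher in both genotypes (976) follow the line up to 6.04, where AT3G02840 lies, while many falls were called in 1 genotype.

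Whether the mutant responded differently was tested as the difference between its response and that of wild type. Limma called 0 probe sets for this difference, with a lowest adjusted p of 0.975; 859 had an unadjusted p under 0.05, against 934 given by chance. On simulated values with this design, 83.0% of 2-fold and 100% of 4-fold differences between the responses were recovered. The changed probe sets all lay well above the floor and the noise was independent, so this does not cover dimmer probe sets. The difference for STZ was 0.01 ± 0.25 (SE), for WRKY53 0.44 ± 0.20, for PUB22 -0.04 ± 0.29, for CML42 0.21 ± 0.15 and for AT1G24140 -0.18 ± 0.11. The 5 genes with the lowest p for a more positive response in the mutant, none of which passed (adjusted p = 0.975 each), were AT5G05230 (0.64), AT4G17470 (0.62), AT4G36580 (0.62), AT1G50280 (0.62) and AT5G08360 (0.64). Those for a more negative response, which did not pass either, were AT2G39430 (-0.78), AT2G12910 (-1.01), AT4G26880 (-1.13), AT2G16630 (-0.45) and the peroxidase gene AT1G44970 (-0.60). With array 2 of water-treated mutant left out, 1 probe set was called for the difference.

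None of the 11 gene lists tested differed between the responses (lowest camera adjusted p = 0.375; 1 list at an unadjusted camera p under 0.05, 0 with an estimated correlation and 0 with fry). Adjusted over the list alone, PUB24 (0.35), XTH19 (-0.36), CCR2 (0.33, from bounds) and the defensin gene PDF1.2 (2.19) passed, and over all probe sets they did not, each with an adjusted p of 0.975. The size of the whole response was compared over the 679 probe sets called for the average chitooctaose effect with a change of at least 2-fold. Their median change in the direction of the effect was 1.80 in wild type and 1.84 in the mutant, with a median difference of 0.05 that fry did not separate from 0, at a p of 0.343. As mutant minus wild type, the 635 of them that rose had a median difference of 0.04, with a camera p of 0.0122 (p = 0.308 with an estimated correlation), and the 44 that fell -0.07, toward a larger fall in the mutant, with a camera p of 0.3 (p = 0.526 with an estimated correlation). With the deposited values as they were, the median difference was 0.15 and the fry p 0.00841; in that setting the median of all probe sets was also shifted, by 0.10, and relative to it the difference was 0.05, as it was in the normalized values.

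The genotypes were compared in water to ask which transcripts differed before the elicitor. QQS, an Arabidopsis orphan gene linked to starch content, was lower in the mutant by -1.62 ± 0.15 (log2, SE, n = 3 arrays per group; adjusted p = 0.00284), with all 3 mutant arrays below all 3 wild-type arrays. AT5G55570 was higher in the mutant by 1.25 ± 0.15 (adjusted p = 0.0144), close to the floor in wild type; its call was lost without any 1 of the 3 wild-type water arrays (adjusted p = 0.0633, 0.0887 and 0.104) or mutant water array 1 or 2 (adjusted p = 0.0861 and 0.0792). The AT5G55570 call in water was also lost with floor-constant probe sets kept (adjusted p = 0.111), with only the arrays compared (0.119) and without both wild-type arrays that stood apart (0.0628), and its value was 0.60 with the offset. Limma called 6 probe sets in all, 4 higher and 2 lower in the mutant, with 1130 at an unadjusted p under 0.05 against 934 given by chance. The other 4 were not assigned to a single gene in the table used here and were singled out after their values were seen. Whether those with no listed gene measure ERF5 or ERF6 cannot be told from that table. A probe set with no listed gene was lower in the mutant, at -2.04 ± 0.11, and rose with chitooctaose by 4.71 in wild type and 4.32 in the mutant. In mutant water it was near the floor, at an intensity of 16.95, and with the offset it had -1.11 in water and was the 1 probe set called for the difference between the responses (-1.22, adjusted p = 0.00205, against -0.40, adjusted p = 0.997). A pair of probe sets that match several genes each were higher, by 2.51 ± 0.15 and 1.07 ± 0.10, and 1 more with no listed gene was higher by 0.93 ± 0.11, a call lost without mutant water array 2 or 3 (adjusted p = 0.0726 and 0.0857) or wild-type water array 1 or 3 (adjusted p = 0.0719 and 0.104), with floor-constant probe sets kept (adjusted p = 0.0814), with only the arrays compared (0.232) or without both wild-type arrays that stood apart (0.087). None of the 11 gene lists passed (camera, lowest adjusted p = 0.121; 2 at an unadjusted p under 0.05, 0 with an estimated correlation, and with fry 0 adjusted and 1 unadjusted); 1 passed without mutant water array 1 or 2, and 2 with floor-constant probe sets kept.

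After chitooctaose the difference in QQS was -2.12 ± 0.15 (adjusted p = 0.000289), again with no overlap of the arrays, and its normalized intensity was 264 in wild type and 60.7 in the mutant. Of the 4 probe sets limma called, QQS alone was assigned to 1 gene. The others, all called in water too, were the lower probe set with no listed gene (-2.44 ± 0.11) and the pair that match several genes each (2.01 ± 0.15 and 0.89 ± 0.10). The last call was lost without mutant chitooctaose array 1 or 2 (adjusted p = 0.149 and 0.0817) or wild-type chitooctaose array 2 or 3 (adjusted p = 0.116 and 0.122), with only the arrays compared (0.182) or without both wild-type arrays that stood apart (0.172). At an unadjusted p under 0.05, 1207 probe sets were counted. The jasmonate- and ethylene-inducible defensin gene PDF1.2 was 2.65 ± 0.56 higher in the mutant, which did not pass over all probe sets (adjusted p = 0.395); PDF1.2b had 1.24 ± 0.44 (adjusted p = 0.662), and both passed when adjusted over their list alone. None of the 11 gene lists passed (camera, lowest adjusted p = 0.384; 1 at an unadjusted p under 0.05, 0 with an estimated correlation, and with fry 0 adjusted and 1 unadjusted).

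Averaged over both treatments, QQS was -1.87 ± 0.11 lower in the mutant (n = 6 arrays per genotype, adjusted p = 1.99e-05), AT5G55570 0.86 ± 0.10 higher (adjusted p = 0.0184) and AT5G23830 0.49 ± 0.06 higher (adjusted p = 0.0217). Both AT5G55570 and AT5G23830 lie on chromosome 5, as does ERF5, but their distances from ERF5 were not compared. With QQS, these were the 3 probe sets with a single gene among 7 called, 5 higher and 2 lower; 1511 had an unadjusted p under 0.05. The AT5G23830 call held without mutant chitooctaose array 2 or wild-type chitooctaose array 1 or 2, and was lost without any of the other 9 arrays (adjusted p up to 0.0987, without mutant chitooctaose array 3). That of AT5G55570 was lost without mutant water array 1 or 2 (adjusted p = 0.0573 and 0.0537), wild-type water array 2 or 3 (adjusted p = 0.0613 and 0.0791) or wild-type chitooctaose array 3 (adjusted p = 0.0617), and with floor-constant probe sets kept (adjusted p = 0.0758). Without both wild-type arrays that stood apart, the adjusted p for the average was 0.0891 for AT5G55570 and 0.119 for AT5G23830. The value of AT5G55570 was 0.42 with the offset. In chitooctaose alone AT5G55570 was 0.47 higher and not called (limma adjusted p = 0.608), against 1.25 in water, so its average came mainly from the water arrays. The count was 4 without wild-type water array 3 and 12 without wild-type chitooctaose array 2. Among the 11 gene lists camera called 0 for this average (lowest adjusted p = 0.612), with 0 at an unadjusted p under 0.05, and fry called 0 with 1 at an unadjusted p under 0.05.

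**Figure D3:**
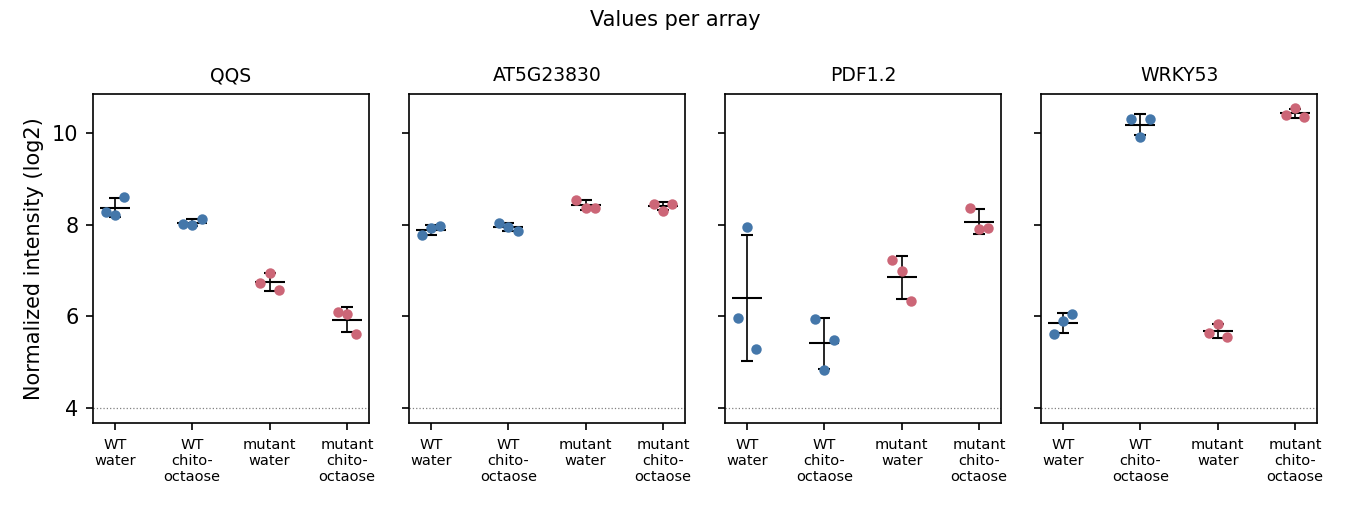
Normalized intensity (log2) of QQS, AT5G23830, PDF1.2 and WRKY53 on each array; points are the 3 arrays of each group, horizontal lines their means with bars of 1 SD, and the dotted line is the floor. QQS is lower on all 6 mutant arrays than on all 6 wild-type arrays, PDF1.2 spreads widely in water-treated wild type (SD 1.38), and WRKY53 rises in both genotypes.

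The average effect of chitooctaose over both genotypes rests on 6 arrays per treatment. Limma called 3166 probe sets, 1402 higher and 1764 lower (55.7% lower); 635 rose and 44 fell by at least 2-fold. The split between higher and lower depended on the scaling: with the deposited values as they were, 1484 were higher and 881 lower (37.3% lower), and with each array centred on its median, 1445 and 1211 (45.6% lower). Array weights gave 2708 lower. Camera called the WRKY, ubiquitin ligase, calcium signalling and oxidative burst lists for this average, and 3 of these 4 also with an estimated correlation; the oxidative burst list went from an adjusted p of 0.0138 to adjusted p = 0.0605 with an estimated correlation.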

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

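The 3 family lists below were set up after the data had first been examined, and no test of an explanation was run on them. In each, the response to chitooctaose differed between the genotypes by a camera test of the difference itself, with no single member called. The 48 class III peroxidase genes had a median difference of -0.11 (mutant response minus wild-type response, -0.112 unrounded; adjusted p = 0.00836, and adjusted p = 0.662 with an estimated correlation; fry adjusted p = 0.459), and the call was lost without wild-type water array 1 (median -0.0421, adjusted p = 0.199), mutant water array 2 (adjusted p = 0.0597) or wild-type chitooctaose array 2 (adjusted p = 0.0557), with array weights (median -0.0894, adjusted p = 0.148), and without both wild-type arrays that stood apart (adjusted p = 0.2), an alternative chosen after seeing the data. The 39 UDP-glycosyltransferase genes had a median difference of -0.133 (adjusted p = 0.00836, and adjusted p = 0.111 with an estimated correlation; fry adjusted p = 0.0252), lost without wild-type chitooctaose array 2 (adjusted p = 0.0593) or without both wild-type arrays that stood apart (adjusted p = 0.0592). The 67 plastid-encoded genes had a median difference of 0.0902 (adjusted p = 0.00999, and adjusted p = 0.959 with an estimated correlation; fry adjusted p = 0.949), lost without mutant water array 2 (adjusted p = 0.115) or 3 (0.305), mutant chitooctaose array 3 (0.475), wild-type water array 3 (0.435) or wild-type chitooctaose array 2 (0.0593), and with array weights (median 0.0411, adjusted p = 0.148).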

How the results depend on the processing

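Keeping the probe sets at the floor on all arrays, and leaving out both wild-type arrays that stood apart on component 2, were chosen after seeing the data; the other alternatives were planned. QQS kept its call and direction under every alternative run (highest adjusted p 0.0485 in water, 0.0122 in chitooctaose and 0.000844 for the average). Leaving out each array in turn gave 1320 to 1945 probe sets for the wild-type response (354 to 830 of them lower), 1288 to 1749 for the mutant response (302 to 595 lower), 0 to 1 for the difference between the responses, 4 to 9 for genotype in water, 3 to 6 for genotype in chitooctaose, 2515 to 3320 for average chitooctaose and 4 to 12 for average genotype. Without single arrays the size of the response lay between 0.00943 and 0.0812, 90 to 96 of 97 calls of named genes were kept, and 3 to 5 gene lists were called in wild type, 4 in the mutant, 0 for the difference, 0 to 1 for genotype in water and 0 for genotype in chitooctaose.

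A 2-fold minimum left 665 probe sets in wild type, 696 in the mutant, 679 for average chitooctaose and 3 for average genotype, which follows from the stricter criterion. An offset of 32 in place of the floor called 1 probe set for the difference between the responses and 17 for average genotype. In genotype in chitooctaose, array weights called 7 and keeping floor-constant probe sets 7. Average genotype had 11 calls each without the dimmest probe sets, with an intensity trend and with array weights. In wild type 5 gene lists were called without the dimmest probe sets, 5 with the offset and 5 with only the arrays compared. The size of the response was 0.152 with values as deposited, at a fry p of 0.00841, and -0.011, reversed in sign and at a p of 0.63, with no minimum change. Except for the stricter criterion, the cause was not tested.

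With the replicate number as a block there were 1823 probe sets in wild type, 1517 in the mutant, 0 for the difference, 5 for genotype in water, 6 in chitooctaose, 3091 for average chitooctaose and 8 for average genotype, and a response size of 0.0427; besides AT5G23830 (adjusted p = 0.0743), the block ended the call in water of the probe set with no listed gene that was higher in the mutant (adjusted p = 0.0613) and, among the lists added later, the calls of xyloglucan transferases in wild type (0.0688) and for genotype in water (0.0544), which other settings ended too, and no other call of a named gene or list. The numbers do not pair the arrays: same-numbered arrays correlated between -0.29 and 0.45 in their deviations from group means, and 0 to 2 of 3 were best with their own number. Without both wild-type arrays there were 1422 probe sets in wild type, 1743 in the mutant, 0 for the difference, 4 and 3 for genotype, 2699 and 5 for the averages, and a response size of 0.0843. ERF5 and ERF6 levels gave no value under any setting, since the gene table used here named no probe set for them. That table left 8730 of the 22746 probe sets without a gene, so probe sets that measure ERF5 or ERF6 may be among those, unrecognized. About 24% of values lay below the floor, so falls of dim transcripts were bounded there.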

Other observations

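Chosen only after the result was seen were the family lists, both tests on QQS, both tests on PDF1.2, and the test of weaker repression among the falls. Genes of the VQ-motif family, small regulators that bind WRKY factors, rose as a group with chitooctaose. Of 9 measured members, 7 rose in each genotype (camera adjusted p = 3.87e-12 in wild type and 1.14e-12 in the mutant, and adjusted p = 0.00848 and 0.00737 with an estimated correlation). Next to AT2G22880, AT4G20000 rose by 4.20 in wild type and 4.19 in the mutant, AT1G78410 by 3.85 and 4.03, and AT5G46780 by 1.68 and 1.96. Of 16 berberine bridge enzyme-like oxidase genes 5 rose in each genotype, among them AT1G30700 (2.69 and 2.91), AT1G26420 (2.61 and 2.81) and AT4G20830 (1.88 and 1.82). Their camera adjusted p was 0.000115 in wild type and 1.19e-05 in the mutant, lost with an estimated correlation (adjusted p = 0.166 and 0.111 with an estimated correlation).

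Of 21 receptor kinase genes of the LRR-I malectin-like family, 4 rose in wild type and 6 in the mutant, among them AT1G51890 (1.23 in wild type and 1.77 in the mutant) and AT5G59680 (1.45 and 1.39). The camera adjusted p of 0.0044 and 0.000579 was lost with an estimated correlation (adjusted p = 0.166 and 0.114 with an estimated correlation), and no member differed between the responses. Among single genes, the tetraspanin genes TET9 and TET8 rose by 2.66 and 2.04 in wild type and 2.69 and 1.93 in the mutant. BZIP60, a transcription factor of the endoplasmic reticulum stress response, rose by 1.55 and 1.46, and the glycosyltransferase gene UGT73B5 by 1.62 and 1.57. Of 8 xyloglucan transferase genes 2 rose in wild type, with a camera adjusted p of 0.0366 for the list (adjusted p = 0.166 with an estimated correlation). That call was also lost without the dimmest probe sets (adjusted p = 0.0586), with only the arrays compared (0.0575), without both wild-type arrays that stood apart (0.0904), and without mutant chitooctaose array 2 (0.0553), wild-type water array 1 (0.061) or wild-type chitooctaose array 2 or 3 (0.0602 and 0.0551). The 67 plastid-encoded genes had a median of 0.084 in the mutant response with 0 called (camera adjusted p = 0.00356, and adjusted p = 0.811 with an estimated correlation), lost with array weights (0.057) and without mutant array 3 of water (0.252) or chitooctaose (0.229). Of the 31 added lists, camera called 3 for genotype in water, 1 in chitooctaose and 0 for the average, with no single member called, 0 of them with an estimated correlation and 0 with fry. In water the median difference of class III peroxidases was 0.133 (adjusted p = 0.00358, and adjusted p = 0.415 with an estimated correlation), lost with array weights (0.0666) and without mutant water array 3 (0.0515), wild-type water array 1 (0.104) or both wild-type arrays that stood apart (0.0889). Nuclear-encoded photosynthesis genes had 0.0898 (adjusted p = 0.00736, and adjusted p = 0.415 with an estimated correlation), lost without mutant water array 1 or 2 (0.0597 and 0.0507) or wild-type water array 3 (0.0651). Xyloglucan transferases had 0.192 in water (adjusted p = 0.016, and adjusted p = 0.242 with an estimated correlation), lost with array weights (0.0503) and without mutant or wild-type water array 3 (0.104 and 0.0544). In chitooctaose plastid-encoded genes had 0.0758 (adjusted p = 0.00564, and adjusted p = 0.801 with an estimated correlation), lost without mutant array 3 (0.366), wild-type array 2 (0.123) or both wild-type arrays that stood apart (0.132).

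Other groupings of the arrays were counted for each comparison. With 10 splits of 6 arrays a share under 0.05 cannot be reached: the real split gave 1894 calls in wild type (highest other 0; 1 of 10 as large), 1608 in the mutant (highest other 1; 1 of 10), 6 for genotype in water (highest other 1; 1 of 10) and 4 for genotype in chitooctaose (highest other 5; 2 of 10). Over 100 drawn splits of all 12 arrays, the real split alone gave as many calls for both averages, 1 of 100 and so under 0.05. It gave 3166 calls for chitooctaose (highest other 1) and 7 for genotype (highest other 3). Splits for chitooctaose that mix water and treated arrays carry the treatment effect in their spread, so few calls in them were built in. The genotype share concerns the count of calls alone. Among those calls, AT5G55570, AT5G23830 and an unnamed probe set lost theirs without single arrays. For the difference between the responses the real split called 0, so 100 of 100 gave as many by construction (highest other 7) and the count says nothing.

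QQS was lower on all 6 mutant arrays than on all 6 wild-type arrays. A chromosome segment of another background carried along with the targeted loci is argued against, since 0 of the 2 loci lie on the chromosome of QQS, which is 3 (ERF5 is on 5 and ERF6 on 4). Under the other scalings the difference nearest to 0 was -1.855 with a standard error of 0.10, against -1.87. The deposited array medians lay between 76.96 and 83.25, so rescaling whole arrays could move the difference only little. That it stayed was therefore largely built in. A segment stays open for AT5G55570 and AT5G23830, which were higher in the mutant and lie on chromosome 5, as does ERF5. Only the chromosome was compared, not the distance from ERF5, so sharing it is no evidence for a carried segment. For QQS what stays open is an effect of the mutations on QQS, or another difference between the lines, such as the epigenetic state that is known to vary at this gene; neither was tested.

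Falls were shared less often between the genotypes than rises, 29.8% against 86.2% of the calls in wild type, and with single arrays left out 23.4% to 47.2% against 81.6% to 91.5%. The smaller estimated size of the falls did not account for the whole gap, while a smaller true size stays open as its cause. Rises matched in size were shared in 60.7% (central 95% of 1000 draws 57.3% to 63.8%) against 30.1% of the matched falls. In the mutant these values were 69.2% and 45.7%. The matching was on the estimated size alone, in the genotype that made the call, not on spread or intensity. Estimates of calls that only just passed the threshold tend to be too large. Equal estimates therefore need not mean equal true sizes, and the matching does not cover such falls. Among changes of at least 2-fold, 76.5% and 55.3% of falls were shared against 94.1% and 91.5% of rises. Those falls numbered 34 in wild type and 47 in the mutant. The 2-fold cut was applied in both genotypes. Called falls of 4-fold numbered 0 in either genotype, against 283 rises in wild type and 295 in the mutant. Falls thus lay nearer the cut than many rises, so a lower shared part of falls was partly built in. Without the 2 wild-type arrays that stood apart, the shared part of the falls was 40.8% in wild type and 30.8% in the mutant. Of the rises 90.3% and 76.6% were shared, so a gap remained. The fit then had fewer wild-type arrays and called 449 falls in wild type against 762, which by itself can lower the shared part. A part played by those arrays therefore stays open. Array scaling stays open for the size of the gap, not for its direction: 19.8% and 65% of falls against 91.9% and 79.6% of rises were shared in wild type and mutant with the values as deposited, and 33.2% and 44.4% against 86.9% and 88.4% with median centring. Weaker repression in the mutant stays open. Over the 1764 probe sets that fell on average, the median difference between the responses was 0.04 with a fry p of 0.0762. The 1402 that rose on average had 0.02, also above 0, with a fry p of 0.497. A shift common to rises and falls was therefore not told apart from weaker repression. The 44 that fell at least 2-fold had -0.07, the opposite direction, at a camera p of 0.3.

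PDF1.2 was 2.65 higher in the mutant than in wild type after chitooctaose, with an adjusted p of 0.395 over all probe sets. A single array is argued against, since the smallest difference with 1 of the 6 arrays left out was 2.36. Higher jasmonate pathway transcripts in the mutant after chitooctaose stay open: OPCL1, MYC3 and MYC4 had a median genotype difference of 0.143, but they are 3 of 31 listed genes, and the bound was set after the result was seen. Chance among 18680 probe sets stays open, as does a change limited to defensin genes, which is a hypothesis that PDF1.2b, at 1.24 with an adjusted p of 0.662, leaves undecided.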
